A study of Mus musculus with 8 samples.

How the data were processed

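Submandibular glands of male mice were profiled by RNA sequencing in 8 libraries, 4 from wild-type C57BL/6J mice (WT) and 4 from Dp16 mice. Per the labels, glands were freed of surrounding connective and fat tissue, total RNA was isolated with a column kit, and libraries were made with a stranded total RNA kit with ribosomal RNA depletion. The deposited values are whole-number read counts per gene, 1 table per library, identified by Ensembl gene number. The submitters' processing notes name FastQC, STAR, HTSeq, DESeq2 and the mouse build GRCm38, with no versions and no order. The annotation release and the strand setting of the counting are not given in the sources used here. A library kit of this kind keeps unspliced transcripts, and reads from a gene and an overlapping antisense partner can be separated only if strand was used in counting. Reads shared by near-identical copies align more than once and are counted in a row that names no gene, so members of families such as the kallikrein-related genes and the H2-Q genes are uncertain.

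Each table held 54838 genes and 5 rows that name no gene. Those 5 rows were left out of library sizes and tests. They held 58.1% to 65.4% of the reads of a library. Most were reads with more than 1 alignment (35.8% to 43.9%) and reads overlapping no counted feature (13.8% to 20.8%). The latter can include reads from introns of annotated genes. Gene names, biotypes and coordinates came from GENCODE M21 on GRCm38, to which 54723 of the genes matched and 115 did not. The duplicated segment was taken from the start of Lipi to the end of Zbtb21, chromosome 16 from 75540514 to 97962622.

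Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing the default expression filter of edgeR were kept (19358 genes, of which 127 lie in the duplicated segment), library sizes were scaled by TMM, and genotype was tested with the quasi-likelihood F-test (glmQLFit and glmQLFTest) with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested and called at an adjusted p below 0.05. Standard errors and 95% confidence intervals of log2 fold changes come from the same fit. All tests were two-sided. Per-gene levels are TMM-scaled CPM, the count as it would be at a common library size, given as mean ± SD of 4 libraries, and log2 CPM used a prior count of 2. Each triplicated gene was also tested against a fold of 1.5, the ratio of 3 copies to 2. Medians over gene sets were tested by exact permutation of the genotype labels over all 35 splits of 8 libraries into 4 and 4, for which the smallest possible p is 0.0286.

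Of 34 gene lists, 31 were tested with camera from limma 3.58.1, with the preset correlation of 0.01 between genes. The 2 lists of sex-linked genes and a list of skeletal muscle genes with 4 members tested, under the minimum of 5, were not. P-values were adjusted over the lists. Camera with an estimated correlation and fry, which tests a list without comparing it with other genes, were run beside it. Fry results are those of its test for a shared direction, except where its mixed test is named. A list's score in a library is the mean log2 CPM of its members minus the WT mean. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes 12 triplicated genes and 11 genes of calcium signalling and fluid secretion whatever their values, and outside the duplication the 10 largest changes in each direction among called protein-coding genes with official names, a mean log2 CPM of at least 0 and groups that do not overlap. It also takes up to 4 members of each list by smallest p, and the Y-linked genes with Xist as a check of sex. An exact permutation of each list's score was chosen after seeing the data.

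The alternatives were DESeq2 1.42.0, size factors by relative log expression, TMM without the 1% most abundant genes, no expression filter, a filter of CPM of at least 1 in 4 libraries, limma-voom with quality weights, an adjusted p below 0.10, the replicate number as a block, 1 surrogate variable from sva 3.50.0, each library left out in turn, and the list tests named above. DESeq2 was run without the edgeR filter, so its counts per list are over the members to which it gave an adjusted p. Camera was also run without the triplicated genes, and the interval was used in place of the name list of triplicated genes.

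The fits were tested on simulated data with the means, dispersions and library sizes of the 8 libraries and 200 genes changed between the 4 Dp16 and 4 WT libraries. The changed genes were drawn from those with a mean CPM of at least 1, so recovery of lower genes was not measured. On 19009 genes, edgeR recovered 24.4% of the genes changed 1.5-fold, 68.4% of those changed 2-fold and 94.7% of those changed 4-fold, with 6 false calls among 120. DESeq2, run on 19358 genes, recovered 44.2%, 89.5% and 96.5%, with 70 false calls among 214. Camera called the simulated list of 86 genes changed 1.5-fold and 0 of 30 unchanged lists. The genes of an unchanged simulated list varied independently, which real genes do not.

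Reads counted in genes ranged from 90790542 to 115729892 per library, so counting error is small for all but the lowest genes and the spread between libraries sets the precision. The labels do not say whether the libraries came from separate animals. The p-values then measure only the spread between these samples, which may be technical.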

Results

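Gene expression in the submandibular gland, a major salivary gland, was compared between WT and Dp16 male mice, with 4 libraries each. Dp16 mice carry a duplication of the part of mouse chromosome 16 between Lipi and Zbtb21, which matches much of human chromosome 21 and gives its genes 3 copies instead of 2. They are a model of Down syndrome. The title of the series names calcium and reduced salivation as its subject. Genes counted per library ranged from 25566 to 26709, with 90790542 to 115729892 reads in genes. Mucl2, a secreted mucin-like product of the gland, took 25.8% of gene reads on average over the 8 libraries. The 10 most abundant genes together took 45.7% to 53.0%. Reads overlapping no counted feature took 14.98% ± 0.964 of all reads in WT and 19.8% ± 1.16 in Dp16 (SD, n = 4 each). The difference of 4.81 percentage points was reached by 1 of 35 splits (exact permutation p = 0.0286). Correlations of log2 CPM were 0.966 to 0.983 within groups and 0.959 to 0.981 between groups. Replicates differed by more than sampling noise in each pair, with a chi-square per degree of freedom of at least 86.7. All 4 Y-linked genes examined were detected in each library, with Ddx3y at 57.01 ± 3.22 CPM in WT and 54.0 ± 4.03 in Dp16 and Uty at 47.6 ± 2.68 and 47.0 ± 5.10 (SD, n = 4), and Xist, expressed in females, had 1 to 8 reads per library. By edgeR, 0 of the 4 Y-linked genes were called over all genes or when adjusted over the list alone, 1 had an unadjusted p below 0.05, and DESeq2 and limma-voom called 0.

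The first question was whether genes with 3 copies were expressed above the WT level. Of the 86 triplicated genes tested, 83 had a positive log2 fold change, with a median of 0.59 (quartiles 0.41 and 0.80), a fold of 1.51. No other split of the libraries gave a median as large (1 of 35 splits, exact permutation p = 0.0286, highest other 0.31). The median was 0.57, 0.54, 0.57 and 0.60 in Dp16 replicates 1 to 4 against the WT mean. By edgeR, 28 of the 86 rose and 0 fell at an adjusted p below 0.05, and 69 rose and 1 fell when adjusted over the list alone. Son, an RNA splicing cofactor, had the smallest p (log2 fold change 0.93, SE 0.078, edgeR adjusted p = 0.0111), from 305 ± 9.03 to 582 ± 9.99 CPM (SD, n = 4 each). App, the amyloid precursor protein gene at chromosome 16 from 84949685 to 85173766 on GRCm38, rose from 629 ± 64.3 to 998 ± 67.0 CPM (0.67, SE 0.11, edgeR adjusted p = 0.0428). The interferon receptor genes Ifnar1 (0.54), Ifnar2 (0.79) and Ifngr2 (0.61) rose, as did the kinase gene Dyrk1a (0.47), the protease gene Tmprss2 (0.91) and the potassium channel gene Kcnj15 (0.69), with edgeR adjusted p-values of 0.0276, 0.0122, 0.0265, 0.0265, 0.0437 and 0.0467. Sod1, superoxide dismutase, had 0.43 (SE 0.078, edgeR adjusted p = 0.0507), and the calcineurin regulator Rcan1 had 0.70 (SE 0.161, edgeR adjusted p = 0.071). Il10rb (0.41), Itsn1 (0.53) and Ets2 (0.23) did not pass, with edgeR adjusted p-values of 0.101, 0.0909 and 0.115. Against a fold of 1.5, adjusted over the list alone, 1 gene lay above (Son) and 9 below, among them Ets2. The 45 tested orthologs of human chromosome 21 genes that lie elsewhere in the mouse genome, with 2 copies in both genotypes, had a median log2 fold change of -0.06 and a mean of 0.01. A median of this size was reached by 7 of 35 splits (exact permutation p = 0.2). Of these 45, 0 were called by edgeR over all genes, and 2 rose and 5 fell when adjusted over the list alone, with 14 at an unadjusted p below 0.05, DESeq2 calling 3 higher and 5 lower, and limma-voom 3 lower. Their median was -0.10 without WT replicate 1, -0.13 without WT replicate 3 and -0.10 without Dp16 replicate 3. Pofut2 had -0.55 and Sik1 had -0.91, with edgeR adjusted p-values of 0.0648 and 0.0683. Protein-coding genes of chromosome 16 outside the segment had a median of -0.05 (365 genes, 1 of 35 splits, exact permutation p = 0.0286). The margin was small: the median log2 CPM difference was -0.051, and the highest other split reached 0.048 in size. Over the 14337 protein-coding genes outside the segment on all chromosomes the median log2 fold change was -0.03. The number of triplicated genes called depended on single libraries: by edgeR it was 14, 0, 3 and 3 without WT replicates 1, 2, 3 and 4, and 0, 40, 21 and 6 without Dp16 replicates 1, 2, 3 and 4. It was 59 by DESeq2 and 43 by limma-voom, and 72 of the 86 had an unadjusted p below 0.05, as did 24.6% of all genes tested.

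**Figure D1:**
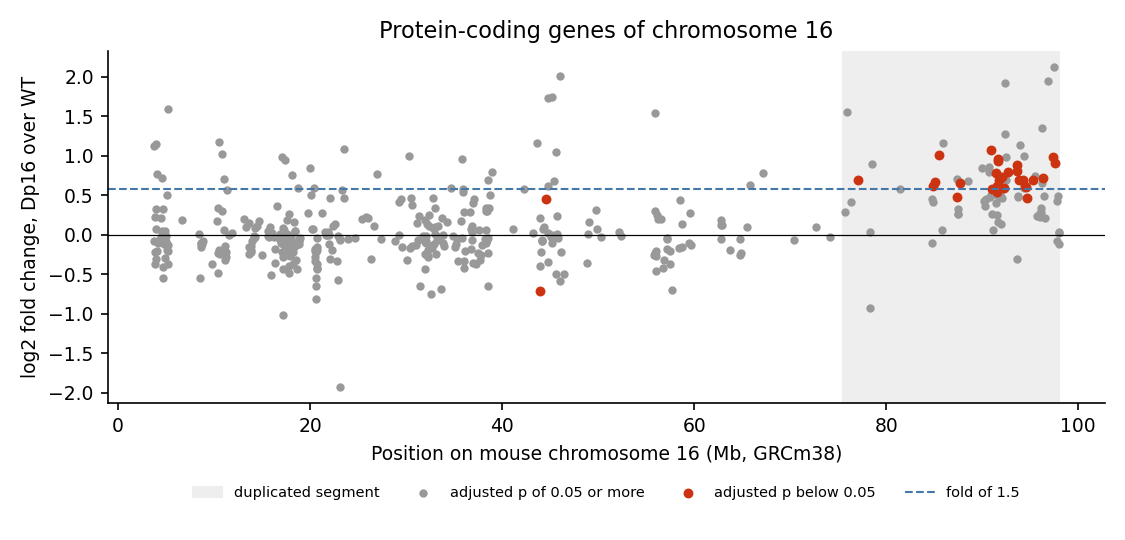
Log2 fold change (Dp16 over WT) of each tested protein-coding gene against its position on chromosome 16 in megabases (GRCm38), with the duplicated segment shaded and the fold of 1.5 as a dashed line. Red points have an edgeR adjusted p below 0.05, and 28 of the 88 protein-coding genes tested in the segment are red, all above 0.

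Across all 19358 genes tested, edgeR called 91 higher and 30 lower in Dp16. Of these, 37 lay in the duplicated segment, all higher, and 84 outside it (54 higher and 30 lower). Among called protein-coding genes outside the segment with groups that do not overlap and a mean log2 CPM of at least 0, the largest rises included genes of lymphocytes and natural killer cells: Prkcq, a kinase of T cell receptor signalling (log2 fold change 1.55, SE 0.225), Il18rap, a subunit of the interleukin 18 receptor (1.41, SE 0.24), Klrd1, a natural killer cell receptor (1.39, SE 0.206), and Itgae, an integrin of epithelium-resident T cells (1.28, SE 0.199). Their edgeR adjusted p-values were 0.0306, 0.0428, 0.0331 and 0.0385, and all were lowly expressed, with Prkcq at 0.871 ± 0.16 CPM in WT and 2.55 ± 0.632 in Dp16 (SD, n = 4). Clec2i (1.48), Traf3ip3 (1.40), Zfp941 (1.17) and the interferon-inducible Slfn5 (1.16) rose too, with edgeR adjusted p-values of 0.049, 0.0428, 0.045 and 0.045. H2-Q6 had the largest value of these called genes (1.70, edgeR adjusted p = 0.0388) and shares sequence with other H2-Q genes, so its level is uncertain. The score of the lymphoid list differed by 1.77 between the groups on the log2 scale, which 2 of 35 splits reached (exact permutation p = 0.0571), with a camera adjusted p of 0.524 with an estimated correlation and Dp16 replicate 2 within the WT range. Under the same limits the largest falls were in Nfil3, a transcription factor of the clock and of immune cells (-1.74, SE 0.244, from 22.8 ± 8.15 to 6.80 ± 1.14 CPM), Mmp9, a matrix protease (-1.67, SE 0.265), Piga, of GPI anchor synthesis (-1.12, SE 0.179), and Gclc, of glutathione synthesis (-1.11, SE 0.141, from 49.5 ± 8.78 to 22.9 ± 3.04 CPM). Their edgeR adjusted p-values were 0.0276, 0.0388, 0.0388 and 0.0265. Coq10b (-1.03), Csrnp1 (-0.97), Kbtbd8 (-0.87), Ppan (-0.84), Tmem120b (-0.78) and Rassf10 (-0.72) also fell, with edgeR adjusted p-values between 0.0265 and 0.0428. Groups did not overlap in 14.1% of genes tested, where chance gives 2.86%, and 4766 genes (24.6%) had an unadjusted p below 0.05. The total of 121 calls depended on single libraries: it was 63, 0, 4 and 11 without WT replicates 1, 2, 3 and 4, and 0, 446, 56 and 14 without Dp16 replicates 1, 2, 3 and 4, and where it was 0, edgeR still gave 3376 (without WT replicate 2) and 3583 (without Dp16 replicate 1) genes at an unadjusted p below 0.05. Outside the duplication it was 44, 0, 1 and 8 without WT replicates 1, 2, 3 and 4, and 0, 396, 29 and 8 without Dp16 replicates 1, 2, 3 and 4. DESeq2 called 1991 genes with 57.4% of them higher and limma-voom 396 with 62.4% higher, against 75.2% by edgeR. With the replicate number as a block, edgeR called 776 with 46.4% higher, so the majority turned.

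Calcium signalling and fluid secretion, the subject that the series title names, were compared through fixed genes and 5 lists, in which Orai2 and Camk1d rose and 0 genes fell by edgeR over all genes. Orai2, a pore subunit of store-operated calcium entry, rose from 1.82 ± 0.321 to 4.08 ± 0.415 CPM (log2 fold change 1.16, SE 0.154, edgeR adjusted p = 0.0265), and Camk1d, a calmodulin-dependent kinase, from 6.87 ± 0.476 to 12.6 ± 2.73 CPM (0.88, SE 0.149, edgeR adjusted p = 0.0428; SD, n = 4). Both lost their call in omissions: Orai2 without WT replicates 1 to 4 (edgeR adjusted p = 0.05, 0.0995, 0.0501 and 0.0847) and Dp16 replicates 1 and 4 (0.0867 and 0.0517), and Camk1d without WT replicates 1 to 4 (0.0577, 0.134, 0.119 and 0.107) and Dp16 replicates 1, 3 and 4 (0.134, 0.0594 and 0.0502). Orai1, the main pore subunit of this entry in many cells, had -0.43 (SE 0.097, edgeR adjusted p = 0.0709) and its activator Stim1 had -0.19 (SE 0.059, edgeR adjusted p = 0.111). DESeq2 called both lower (DESeq2 adjusted p = 0.00277 and 0.0292), and limma-voom called Orai1 lower (limma-voom adjusted p = 0.0487). The muscarinic receptor gene Chrm3 (-0.14), the IP3 receptor genes Itpr2 (0.12) and Itpr3 (0.20), and the calcium pump gene Atp2a2 (-0.44) did not pass, with edgeR adjusted p-values of 0.273, 0.353, 0.192 and 0.264. The water channel gene Aqp5 had 106 ± 7.96 CPM in WT and 66.6 ± 12.9 in Dp16 (-0.66, SE 0.131, edgeR adjusted p = 0.0589). DESeq2 called it lower (DESeq2 adjusted p = 0.000547), and limma-voom did not call it. The chloride channel gene Ano1 (-0.23), the cotransporter gene Slc12a2 (0.14) and the potassium channel genes Kcnma1 (0.31) and Kcnn4 (-0.13) had edgeR adjusted p-values of 0.294, 0.684, 0.315 and 0.519. Of the 32 tested genes of agonist-evoked calcium release, 20 were positive and 0 were called over all genes or when adjusted over the list alone, with DESeq2 calling 3 higher and 1 lower (median 0.09, camera adjusted p = 0.429). Calcium entry channels, pumps and exchangers had 1 of 32 called, Orai2, and 1 rose and 1 fell when adjusted over the list alone, with 1 higher and 2 lower by DESeq2 (median 0.03, camera adjusted p = 0.745 in the downward direction, against the sign of the median). Voltage-gated channel subunits had 0 of 14 called over all genes or when adjusted over the list alone, and DESeq2 called 2 higher and 1 lower (median 0.17, camera adjusted p = 0.0829). That list passed without WT replicate 1 (camera adjusted p = 0.0349), WT replicate 3 (0.0323) or Dp16 replicate 2 (0.0212). Calcium-binding proteins and effectors had 1 of 35 called, Camk1d, also when adjusted over the list alone, with 1 higher and 2 lower by DESeq2 (median -0.03, mean 0.02, camera adjusted p = 0.858). Fluid secretion transporters had 0 of 35 called over all genes and 1 lower when adjusted over the list alone (median -0.001, mean 0.03, camera adjusted p = 0.803), and DESeq2 called 1 higher and 2 lower. By limma-voom, 1 entry and pump gene was higher and 1 lower, 1 calcium-binding or effector gene was higher, and 0 genes of the other 3 lists were called. Fry's mixed test, which lets members of a list move in both directions, gave adjusted p-values of 0.00324 for release and 0.00103 for entry and pumps. It gave 0.0138 for calcium-binding proteins and effectors, 0.0959 for voltage-gated channels and 0.2 for fluid secretion. That test does not compare a list with other genes. At an unadjusted p below 0.05, which 24.6% of all genes tested had, edgeR gave 9 release genes, 13 entry and pump genes, 4 voltage-gated channel genes, 8 calcium-binding and effector genes and 10 fluid secretion genes. Counts near that share do not set a list apart. For some single genes these data allow a bound. The 95% confidence interval of the log2 fold change was -0.30 to 0.03 for Chrm3 and -0.05 to 0.30 for Itpr2. It was wider for others, such as -0.953 to 0.077 for Atp2a2 and -0.1 to 0.716 for Kcnma1.

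**Figure D2:**
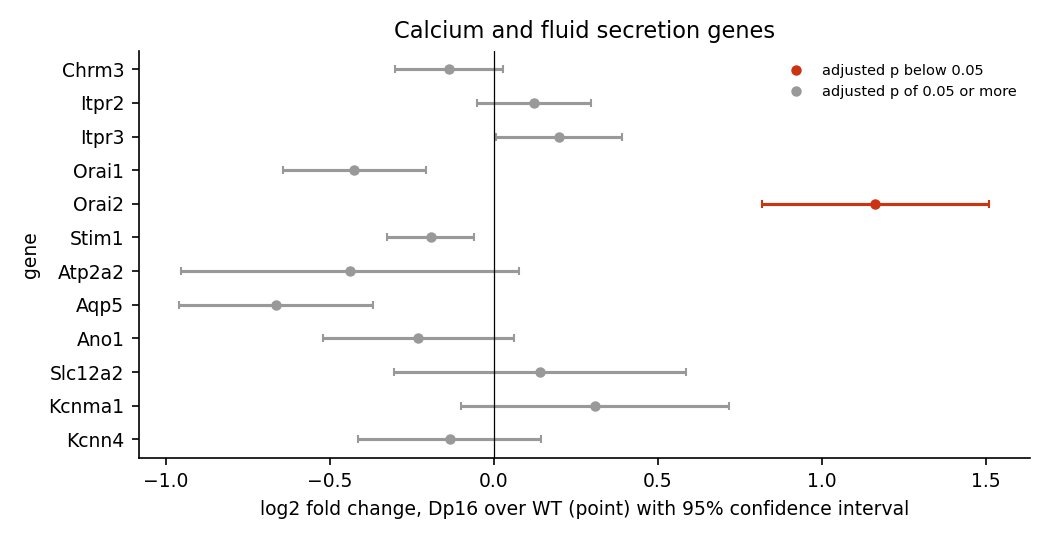
Log2 fold change (Dp16 over WT, point) with its 95% confidence interval from the edgeR fit for 12 genes of calcium signalling and fluid secretion, with 4 libraries per group. Orai2 (1.16), in red, has an edgeR adjusted p below 0.05, and the other 11 do not.

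Lists of gland cell types were compared next. The 25 genes of granular convoluted tubule cells, the ducts that make growth factors and kallikreins in male mice, were negative in 23 cases, with a median log2 fold change of -0.49 (camera adjusted p = 0.000514, adjusted p = 0.524 with an estimated correlation). Klk1, a tissue kallikrein, fell from 1105 ± 52.8 to 680 ± 64.4 CPM (-0.70, SE 0.106, edgeR adjusted p = 0.0358, the 1 gene of the list called over all genes), and 1 rose and 1 fell when adjusted over the list alone. Klk1 lost its call without WT replicates 1 to 4 (edgeR adjusted p = 0.0535, 0.112, 0.0912 and 0.0905) and Dp16 replicates 1 and 4 (0.114 and 0.0598). Its family shares reads among near-identical copies, so these levels are uncertain. Acinar cell genes had a median of -0.24 and a mean of -0.65 over 22 genes, 18 of them negative, with 0 called over all genes and 5 lower when adjusted over the list alone and by DESeq2 (camera adjusted p = 0.0095, adjusted p = 0.524 with an estimated correlation). The acinar median was -0.14 without WT replicate 3 and -0.38 without Dp16 replicate 1. Bhlha15, a transcription factor of secretory cells (-0.83), and Tesc (-0.61) had edgeR adjusted p-values of 0.0589 and 0.058. Other duct markers (24 genes, median 0.04, camera adjusted p = 0.819) and myoepithelial markers (12 genes, median 0.002, mean -0.08, camera adjusted p = 0.693) had 0 genes called over all genes or when adjusted over the list alone, and DESeq2 called 0 duct markers and 1 myoepithelial marker, lower. Krt19 had 0.94 (edgeR adjusted p = 0.223) and Cnn1 had -0.52 (edgeR adjusted p = 0.103). Exocytosis genes had 0 of 30 called over all genes and 1 higher and 2 lower when adjusted over the list alone (median -0.11, camera adjusted p = 0.177), and DESeq2 called 2 in each direction. Rab3a had -0.50 (edgeR adjusted p = 0.0677). Secreted antimicrobial proteins had 0 of 22 called over all genes or when adjusted over the list alone (median 0.07, camera adjusted p = 0.798), and DESeq2 called 2 higher and 1 lower. Pigr, the transporter of polymeric antibodies, had 1.13 (edgeR adjusted p = 0.0943). At an unadjusted p below 0.05, which 24.6% of all genes tested had, edgeR gave 8 granular tubule, 6 acinar, 1 other duct, 3 myoepithelial, 10 exocytosis and 4 antimicrobial genes. By limma-voom 1 granular tubule gene, 1 acinar gene and 1 exocytosis gene were lower, and 0 of the other 3 lists were called.

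The next lists held immune and stromal markers. All 18 tested lymphocyte markers were positive, with a median log2 fold change of 1.99, a fold of 3.99 (camera adjusted p = 3.29e-08, adjusted p = 0.524 with an estimated correlation). Over all genes edgeR called 0 of them, 16 rose when adjusted over the list alone, and DESeq2 called 16 higher. Cd4 had 0.848 ± 0.351 CPM in WT and 2.77 ± 0.711 in Dp16 (1.71, SE 0.351), and Cd79b had 0.786 ± 0.148 and 2.18 ± 0.819 (1.47, SE 0.292), with edgeR adjusted p-values of 0.0609 and 0.0589 (SD, n = 4). The list's score was 2.22, 0.27, 2.94 and 1.64 in Dp16 replicates 1 to 4, against -0.36 to 0.54 in WT, so Dp16 replicate 2 lay within the WT range. Interferon-stimulated genes outside the duplication were positive in 53 of 54 cases, with a median of 0.85 (camera adjusted p = 1.38e-11, adjusted p = 0.524 with an estimated correlation). Of these, edgeR called 0 over all genes, 34 rose when adjusted over the list alone, and DESeq2 called 24 higher. Gbp4 had 1.33 (SE 0.316) and Ddx60 had 1.19 (SE 0.284), both with an edgeR adjusted p of 0.0732. The score was 0.64, 0.30, 1.73 and 0.39 in Dp16 replicates 1 to 4, and the median without Dp16 replicate 3 was 0.43. Endothelial markers had a median of 0.37 (13 of 15 positive, camera adjusted p = 0.00508, adjusted p = 0.524 with an estimated correlation, fry adjusted p = 0.0369), with 0 called over all genes and 3 higher when adjusted over the list alone and by DESeq2. Flt1, a receptor of vascular growth factors, had 0.36 (edgeR adjusted p = 0.0815). Fibroblast and matrix genes had a median of -0.35 (17 of 21 negative, camera adjusted p = 0.012, adjusted p = 0.613 with an estimated correlation), with 0 called over all genes, 1 in each direction when adjusted over the list alone, and 1 higher and 2 lower by DESeq2. The collagen gene Col1a1 had -0.69 and Thy1 had 0.85, with edgeR adjusted p-values of 0.0732 and 0.0846. That list was not called without Dp16 replicate 1 (camera adjusted p = 0.0741, median -0.23) or Dp16 replicate 2 (0.096, median -0.20), and its median was -0.23 without WT replicate 4. Plasma cell genes had 0 of 11 called over all genes and 4 higher when adjusted over the list alone and by DESeq2 (median 0.41, camera adjusted p = 0.0655). That list passed without WT replicate 3 (0.0338) or Dp16 replicate 3 (0.0123), and its median was 0.27 without WT replicate 4. Myeloid markers had 0 of 22 called over all genes, 1 higher when adjusted over the list alone and 2 higher by DESeq2 (median 0.23, camera adjusted p = 0.325), and passed without Dp16 replicate 2 (0.0134), while without Dp16 replicate 3 its median was -0.13 and its direction turned (camera adjusted p = 0.239). With 1 surrogate variable the medians were 1.16 for the lymphocyte, 0.42 for the interferon and 0.21 for the endothelial list, and -0.09 for the myeloid list. Ptprc, a marker of all white blood cells, had 1.03 (edgeR adjusted p = 0.0589). At an unadjusted p below 0.05, which 24.6% of all genes tested had, edgeR gave 16 lymphocyte, 43 interferon, 6 endothelial, 5 fibroblast, 5 plasma cell and 4 myeloid genes. By limma-voom 3 lymphocyte genes, 1 plasma cell gene and 1 myeloid gene were higher, 1 fibroblast gene was lower, and 0 interferon or endothelial genes were called.

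**Figure D3:**
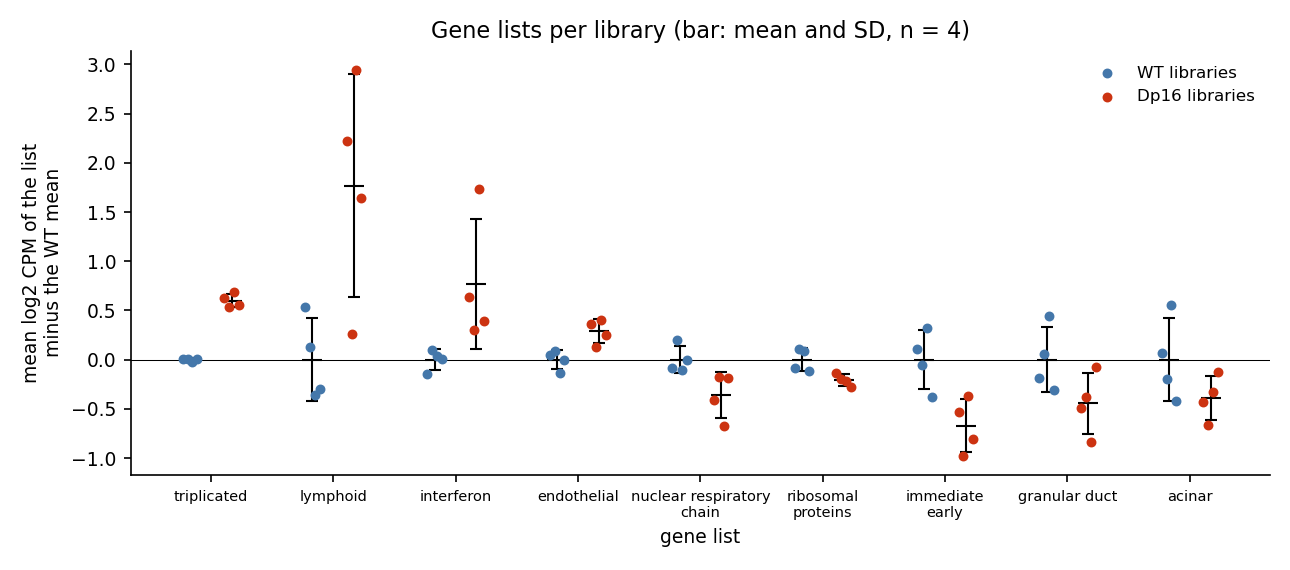
Score of 9 gene lists per library, the mean log2 CPM of the list's members minus the WT mean, with WT libraries in blue and Dp16 libraries in red and bars for the mean and SD of 4 libraries. The triplicated list separates the groups with Dp16 values of 0.54 to 0.69, while the lymphoid list spans 0.27 to 2.94 in Dp16.

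Lists of metabolism, stress and time of day were compared last. All 71 nuclear-encoded respiratory chain genes were negative, with a median log2 fold change of -0.35 (camera adjusted p = 5.62e-17, adjusted p = 0.524 with an estimated correlation). With 1 surrogate variable the median was -0.18. Over all genes edgeR called 0 of them, 40 fell when adjusted over the list alone, and DESeq2 called 22 lower. Cox5a, a cytochrome c oxidase subunit, had 69.1 ± 8.14 CPM in WT and 44.9 ± 8.93 in Dp16 (-0.62, SE 0.148), and Ndufa6, of complex I, had -0.35 (SE 0.079), with edgeR adjusted p-values of 0.0732 and 0.0704. Of 13 mitochondrially encoded genes listed, 9 passed the expression filter. These had 0 of 9 called over all genes, 1 in each direction when adjusted over the list alone and 1 lower by DESeq2 (median -0.18, camera adjusted p = 0.148). As a list they passed without WT replicate 3 (camera adjusted p = 0.0448). Their mt-Nd4 had -0.42 and mt-Nd6 had 0.33, with edgeR adjusted p-values of 0.071 and 0.11. Ribosomal protein genes were negative in 71 of 73 cases (median -0.21, camera adjusted p = 1.38e-11, adjusted p = 0.524 with an estimated correlation), with 0 called over all genes, 3 lower when adjusted over the list alone and 8 lower by DESeq2. Many have processed copies elsewhere in the genome, so their levels are uncertain. Random lists matched on exonic length and mean expression had a median of -0.19 for the respiratory chain and -0.18 for the ribosomal list. Of 10000 such lists, 0% and 21.1% were as low, but their genes were drawn independently, while real members vary together. Reads overlapping no counted feature took 4.81 percentage points more in Dp16. Immediate early genes were negative in 28 of 30 cases (median -0.49, camera adjusted p = 7.37e-07, adjusted p = 0.524 with an estimated correlation), with 0 called over all genes, 1 higher and 14 lower when adjusted over the list alone, and 12 lower by DESeq2. With 1 surrogate variable the median of that list was -0.77. Fos had 6.98 ± 4.58 CPM in WT and 1.14 ± 0.64 in Dp16 (-2.62, SE 0.551), and Nr4a2 had -1.24 (SE 0.243), with edgeR adjusted p-values of 0.0644 and 0.0577. Unfolded protein response genes were negative in 25 of 30 cases (median -0.47, camera adjusted p = 0.000789, adjusted p = 0.613 with an estimated correlation), with 0 called over all genes or when adjusted over the list alone and 2 higher and 3 lower by DESeq2. The median of that list was -0.31 without WT replicate 2, and 0.04 with 1 surrogate variable, where its direction was lost. Herpud1 had -0.47 (edgeR adjusted p = 0.0956). Clock genes had 1 of 20 called, Nfil3, which fell, and 1 rose and 4 fell when adjusted over the list alone (median 0.20, mean -0.05, camera adjusted p = 0.489 in the downward direction), and the median was -0.10 without Dp16 replicate 1. Cell cycle genes had 0 of 30 called over all genes, when adjusted over the list alone or by DESeq2 (median 0.13, camera adjusted p = 0.487). At an unadjusted p below 0.05, which 24.6% of all genes tested had, edgeR gave 50 nuclear respiratory chain, 4 mitochondrially encoded, 34 ribosomal, 17 immediate early, 9 unfolded protein response, 7 clock and 1 cell cycle genes. By limma-voom 2, 1, 1, 3, 1, 1 and 0 of these were called, all lower. Nfil3 lost its call without WT replicates 1 to 3 (edgeR adjusted p = 0.0501, 0.0995 and 0.0705) and Dp16 replicates 1, 3 and 4 (0.1, 0.0565 and 0.0558). Of the 11 lists called with the preset correlation, 4 higher and 7 lower, the triplicated list was the 1 called with an estimated correlation (adjusted p = 0.000404). Fry's test for a shared direction called 2, the triplicated and the endothelial list.

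Markers of neighbouring tissues were measured because they can be carried along at dissection. Sublingual gland markers (5 tested, median -0.02, mean 0.16, camera adjusted p = 0.451), parotid gland markers (5 tested, median 0.08, camera adjusted p = 0.59), adipocyte markers (12 tested, median -0.60, camera adjusted p = 0.351), nerve markers (16 tested, median 0.04, camera adjusted p = 0.489) and red blood cell transcripts (7 tested, median -0.26, camera adjusted p = 0.261) had 0 members called by edgeR over all genes or when adjusted over the list alone. DESeq2 called 1 sublingual and 2 nerve markers higher and 0 of the others, and limma-voom called 0. At an unadjusted p below 0.05, which 24.6% of all genes tested had, edgeR gave 2 sublingual, 0 parotid, 5 adipocyte, 5 nerve and 0 red blood cell genes. The adipocyte median was -0.09 without WT replicate 1 and 0.18 with the stricter filter, which leaves fewer genes, and the sublingual median was 0.69 without WT replicate 3. The red blood cell list passed without Dp16 replicate 3 (camera adjusted p = 0.0388, median -0.43), and its median was -0.03 without Dp16 replicate 2. Muc19, a mucin of the sublingual gland, had 27.3 ± 51.2 CPM in WT and 4.01 ± 6.19 in Dp16 (-2.77, SE 1.803, edgeR adjusted p = 0.361), and 1.26 without WT replicate 3. Adipoq, made by fat cells, had 0.336 ± 0.232 and 0.0870 ± 0.0749 CPM (edgeR adjusted p = 0.147). Of 4 skeletal muscle genes tested, 1 was lower when adjusted over the list alone, Acta1 (-1.79, edgeR adjusted p = 0.104), and DESeq2 called Acta1 lower and Tcap, which did not pass the edgeR filter and was named after its value was seen, higher (2.48, DESeq2 adjusted p = 0.01).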

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

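The tests of lymphocyte markers, and the test of a single Dp16 library for the respiratory chain genes, were chosen after those results were seen. The tests of time of day, stress, unspliced RNA, transcript length and other splits were written before. The values given first lay far from the rest of their group by a rule applied to 404 groups of 4 values. It picked 14 (3.5%), and chance picks about 1 in 20, so the flags are no more than chance gives.

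Among genes, App had a log2 CPM of 10.10 in Dp16 replicate 4 against 9.91 to 9.92 in the other Dp16 libraries, Kcnn4 had 7.38 in Dp16 replicate 1 against 6.931 to 6.997, and Cacna1d had 2.497 in Dp16 replicate 3 against 1.91 to 1.97. Mcm2 had 3.48 and Col6a3 had 6.57 in Dp16 replicate 4, against 3.02 to 3.05 and 5.70 to 5.77, and Dnase1 had 1.21 in Dp16 replicate 2 against 0.25 to 0.31. Among WT libraries, Prkcq had -0.61 in replicate 2 against -0.09 to 0.01, and mt-Nd4 had 8.52 and Bhlhe40 had 6.32 in replicate 3, against 8.79 to 8.80 and 5.76 to 5.82. Coq10b had 3.70, Cd79b had 0.037 and Cx3cr1 had 3.45 in WT replicate 1, against 4.21 to 4.29, -0.49 to -0.40 and 2.90 to 2.95. The score of the triplicated list was -0.023 in WT replicate 3 against 0.006 to 0.01 in the other WT libraries, and the adipocyte score was 0.005 in Dp16 replicate 2 against -0.75 to -0.73 in the other Dp16 libraries.

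Reads overlapping no counted feature, which no comparison of genes uses, took 4.81 percentage points more of the reads in Dp16 than in WT. Each Dp16 library (at least 18.4%) lay above each WT library (at most 15.9%). In 995 tested transcripts awaiting experimental validation that lie inside 1 tested protein-coding gene on its strand, the log2 fold change exceeded that of the host gene by a median of 0.23, 82.5% lay above the host, and no other split reached this median (highest other 0.17). The copy number of transcripts in the segment cannot carry this median, since 2 of the 995 lie there and the excess over the other 993 was 0.23, while effects of duplicated genes on other genes were not tested. A higher share of unspliced RNA in Dp16 libraries may underlie both, and could come from RNA isolation, from nuclear RNA or from the genotype, which these data do not separate.

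Lymphocyte markers had a median log2 fold change of 1.99 and a camera adjusted p of 0.524 with an estimated correlation. A lower share of gland epithelium would raise markers of all other cell types alike, but the highest median among endothelial, fibroblast, nerve and myeloid lists was 0.37, below the lower quartile of the lymphocyte markers (1.58). The median without any 1 Dp16 library was at least 1.48, against 1.99 with all, which argues against 1 library alone, although Dp16 replicate 2 lay within the WT range. Lymph node tissue left on the gland was not decided: of its vessel, stroma and follicle genes, the 3 with at least 20 reads had a median log2 ratio of 2.53, but Cr2 (3.34) and Fcer2a (2.53) are also B cell genes, and Ccl21a, Ccl19, Madcam1 and Glycam1 had 1, 0, 0 and 0 reads in WT and 1, 0, 2 and 9 in Dp16. The remaining gene, Cxcl13, had 0.83, with 17.7 CPM in Dp16 replicate 3, 0.763 to 2.25 in the other Dp16 libraries and 1.28 to 7.58 in WT. Lymph node tissue and more lymphocytes within the gland by genotype, the latter untested, therefore stay open.

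Immediate early genes had a median log2 fold change of -0.49 and a camera adjusted p of 0.524 with an estimated correlation, their score difference was reached by 2 of 35 splits (exact permutation p = 0.0571), and both technical explanations stay open. Clock genes of opposite phase moved apart, by 0.68 between a median of -0.32 for Arntl, Npas2 and Clock and 0.37 for Dbp and 7 others. A different time of day at collection would move them apart too, although Npas2 (0.26), Usp2 (-0.67) and Per2 (-0.19) went against their phase. Among clock genes outside these sets, Per1 (-1.14) and Bhlhe40 (-1.03) fell and Hlf (0.77) rose, with edgeR adjusted p-values of 0.102, 0.0832 and 0.0797. Heat shock genes had a median of -0.41, which is consistent with a different stress before RNA isolation, although 4 of these 8 genes belong to the immediate early list too (median of the other 4, -0.40). Of the genes of the 2 phases and the heat shock genes, edgeR called 0, while DESeq2 called Dnajb1 (adjusted p = 0.00392) and Usp2 (0.0252) lower, and limma-voom called Dnajb1 (0.0448). DESeq2 also called Per1 (adjusted p = 0.00787) and Bhlhe40 (0.0035) lower and Hlf (0.00618) higher. An effect of the genotype was not tested apart from these.

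Respiratory chain genes had values in these tests that are given without an explanation. Of 10000 random lists matched on exonic length and mean expression, 0% had a median as low as -0.35, while the matched lists themselves had a median of -0.19. The random lists drew genes independently, whereas camera estimated a correlation of 0.76 between the respiratory chain genes. Their spread is thus too narrow a reference, and 0% does not show that the list stands apart. The median nearest to 0 with 1 Dp16 library left out was -0.25, without Dp16 replicate 3. Ribosomal protein genes did not stand apart from matched lists, of which 21.1% had a median as low.

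For the number of genes called, 1 of 35 splits of the 8 libraries, the real one, gave 121 genes and the highest other gave 16. The same holds for the triplicated genes called higher (28, highest other 0, 1 of 35 splits) and for genes called outside the duplication (84, highest other 16, 1 of 35 splits). That is the smallest p that 35 splits allow, and these counts overlap, so chance assignment is made unlikely but is not excluded. For the number of lists called with the preset correlation the real split was not extreme: 6 of 35 splits gave at least 11 lists, and the highest other gave 14.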

How the results depend on the processing

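All alternatives in this part were planned. The direction of the triplicated median (0.56 to 0.61) and of the median of 2-copy orthologs (-0.13 to -0.03) was kept in every setting, and the first was 0.59 over all protein-coding genes of the interval. The counts of called genes were not stable, and the cause was not tested except where stated. Genes higher, genes lower, triplicated genes higher and genes outside the duplication numbered 1142, 849, 59 and 1907 by DESeq2, 247, 149, 43 and 337 by limma-voom, and 746, 562, 55 and 1231 at an adjusted p below 0.10, a looser threshold. On simulated data with 200 genes changed, DESeq2 made 70 false calls among 214. It was then run on 19358 genes, against 33168 here. Such a share also depends on how many genes truly change, so it does not carry over to these calls. With no expression filter 158 were higher, 65 lower and 178 outside. With 1 surrogate variable 53 were higher and 46 outside. Of the 121 genes, DESeq2 and limma-voom kept 121, the stricter filter 109 and 1 surrogate variable 53. Leaving out 1 library gave 0 to 354 genes higher, 0 to 92 lower, 0 to 40 triplicated higher and 0 to 396 outside, and the triplicated median was then 0.557 to 0.607 and that of 2-copy orthologs -0.13 to -0.043. Fewer samples lower the power of these fits, and why 446 genes were called without Dp16 replicate 2 was not tested. All 32 named genes called lost the call in at least 1 omission, and 0 of them changed sign. The replicate block gave 360 genes higher, 416 lower and 717 outside, so that 46.4% were higher and the majority turned. It used the numbers of the sample titles, from which the library name of WT replicate 4 differs. Whether these numbers pair the samples was not settled. Same-numbered libraries had weak positive correlations of deviations (0.191, 0.129, 0.078 and 0.105), and not every Dp16 library correlated best with its own number. The number of lists called was 1 with an estimated correlation and 2 by fry.

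The direction of the list test changed in 6 lists and the sign in 7 named genes, none of them called. List medians changed sign in 12 of 31 lists in at least 1 setting, of which 1 was called, the unfolded protein response list (0.04 with 1 surrogate variable). With fry the direction turned for calcium entry and pumps (adjusted p = 0.995) and calcium-binding proteins (0.986). Without single libraries, camera turned for calcium-binding proteins (adjusted p from 0.643 to 0.922 over the omissions), duct (0.663 to 0.949), antimicrobial (0.544 to 0.894), cell cycle (0.0983 to 0.883) and myeloid lists (0.0134 to 0.579). With 1 surrogate variable the log2 fold change was -0.02 for Slc12a2, -0.004 for Kcnma1, -0.16 for Mylpf, -0.18 for Tnnt3 and 0.037 for Uty. It was 0.29 by limma-voom and 0.15 with the replicate block for Slc26a9, and 0.011 for Uty with the stricter filter. Over the omissions it spanned -4.87 to 1.26 for Muc19, -0.34 to 0.44 for Slc26a9, -0.036 to 0.25 for Mylpf, -0.24 to 0.56 for Tnnt3 and -0.07 to 0.049 for Uty. Depth limits the lowest genes, such as Tnnt3, at 0.0674 CPM in WT.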

Other observations

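The exact permutation of list scores in this part was chosen after seeing the data, as were both genes named next. Ighg1, an antibody heavy chain gene annotated as an immunoglobulin constant gene and so outside the rule for named genes, rose from 0.380 ± 0.148 to 3.73 ± 0.937 CPM (log2 fold change 3.30, SE 0.32, edgeR adjusted p = 0.0132; SD, n = 4 each), higher in 4 of 4 Dp16 libraries than in any WT library. St8sia4, a polysialyltransferase gene, rose from 8.44 ± 0.328 to 17.7 ± 2.43 CPM (1.07, SE 0.109, edgeR adjusted p = 0.0154).

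By annotation class, outside the duplication the median log2 fold change was -0.03 over 14337 protein-coding genes, 0.23 over 1301 transcripts awaiting experimental validation and 0.24 over 664 long intergenic RNAs. Of the transcripts awaiting validation, 10 rose and 0 fell. Gm42418, which overlaps a ribosomal RNA repeat, had 1885 ± 1190 CPM in WT and 5637 ± 2470 in Dp16 (1.58, SE 0.431, edgeR adjusted p = 0.0909). By principal components of the 500 most variable genes, the first took 27.0% of the variance and placed Dp16 replicate 2 (-6.00) next to WT replicate 1 (-5.09), with the other Dp16 libraries at 6.97 to 33.0 and the other WT libraries at -17.6 to -13.4.

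The exact permutation of list scores found 5 lists whose real split was the most extreme of 35 (p = 0.0286 each, the smallest possible): triplicated, interferon, nuclear respiratory chain, ribosomal and endothelial. Adjusted over the lists this is 0.183, so no list passed by this test. At this smallest possible p, a list could pass only if many more lists also reached it. The failure is therefore no evidence against these 5 lists. Other lists that camera called with the preset correlation fell short before any adjustment. Score differences as large were reached by 4 of 35 splits for granular tubule genes (exact permutation p = 0.114) and 6 for acinar genes (0.171). For fibroblast genes it was 6 of 35 (0.171) and for unfolded protein response genes 11 of 35 (0.314). The lymphocyte score difference of 1.77 was reached by 2 of 35 splits (exact permutation p = 0.0571).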
